A study of Danio rerio with 2 samples.

How the data were processed

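The series held 2 single-cell RNA-seq libraries of zebrafish heart cells, 1 from fish given metronidazole (MTZ) and 1 from fish given the solvent DMSO. Per the labels' protocols, hearts were digested with collagenase, live cells were sorted for green fluorescence driven by the fli1 promoter, and droplet libraries that count the 3' ends of transcripts were made from the sorted cells. The authors deposited raw UMI counts per gene and cell barcode, 1 matrix per library, made with Cell Ranger 6.1.1 per the file headers. The genome build was GRCz11 per the submitters' processing notes. The annotation release and the rule by which barcodes were called as cells are not given in the sources used here. No further normalization had been applied to the deposited counts, which were whole numbers with different totals in the 2 libraries.

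The feature list had 27420 entries, 1 of them an added GFP sequence that held 0 UMIs in both libraries. Symbols were taken from the feature list, and entries that shared a symbol were summed, which left 26735 symbols. The deposited barcodes numbered 6206 in the DMSO library and 6709 in the MTZ library, and the shallowest had 501 and 503 UMIs. Cells with at least 500 detected genes and at most 10% mitochondrially encoded UMIs were kept, which removed 338 and 290 barcodes for few genes and 6 and 12 for mitochondrial UMIs. Scrublet, run per library in scanpy 1.11.5, called 0 doublets in both libraries, since its automatic thresholds of 0.464 and 0.578 lay above the highest scores of 0.369 and 0.437. Doublet calling had therefore not worked, and doublets remain in every value below.

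Both libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 were used (igraph 0.11.9). Classes were named from 18 marker lists chosen before the data were examined, whereas the scoring of these markers was set afterwards. A marker counted for a cluster when it was detected in at least 10% of its cells and reached at least 0.5 of the highest CPM among clusters. A class needed 3 such markers, and the class with the largest share of its list was taken. Names were withheld where another class had more markers than the own class among the 10 genes of largest fold, computed with 10 CPM added. An endothelial cluster with 3 or more markers of another class in that top 10 was set aside as mixed. Sub-clusters of 1 small endothelial cluster were made at resolution 0.8, a step chosen after the data were seen.

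With 1 library per group there was no test, and no p-value, standard error or number of changed genes was derived from cells. UMIs were summed over the cells of a class and library and expressed as CPM (counts scaled to a common total of 1e6 summed UMIs) with exact Poisson 95% intervals. Folds carry the exact conditional binomial 95% interval of a ratio of 2 Poisson counts, and shares of cells carry exact Clopper-Pearson 95% intervals. A count of 0 allows up to 3 counts. All of these intervals cover counting error only. UMIs of 1 gene can sit in few cells, which the intervals do not hold, so each sum was also taken without the highest cell of each gene, an alternative added after the data were seen. The intervals also leave out the variation between fish, pools of hearts, sorts and library preparations, which 1 library per group cannot show.

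Genes were named by a size rule. In the endothelial-like class these were the 12 genes higher and the 12 lower in the MTZ library whose fold had the interval bound farthest from 1, among genes at 20 CPM or more in 1 library and at least 1.5-fold different. The rule also asked for that difference in 0.5 or more of the named endothelial classes with 50 cells per library and 20 UMIs of the gene; a single endothelial class reached that size, so the condition added nothing. Genes with clone-type names and mitochondrially encoded, ribosomal protein and haemoglobin genes were left out of the names. For a smaller population the 5 highest and 5 lowest genes were taken in the same way. Up to 3 members of each list farthest from no difference were named too, as were fli1a, fli1b, axin2 and lef1 whatever their values. Any other gene given with a value was chosen after its value was seen. Results that needed an item withheld for evaluation were left out. Each of 26 pathway lists was summarised over members at 5 CPM or more in 1 library by the median log2 fold and by the members at least 1.5-fold higher or lower. The interval of a median came from 1000 Poisson draws, and its percentile from 10000 random lists matched on mean expression in 20 bins. That percentile describes these 2 libraries and is not a test.

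Cycling cells were counted as endothelial-like cells with UMIs of at least 2 genes of the G2/M list after each cell was thinned to 2000 UMIs. A narrower count without the 3 genes detected in 10% or more of the thinned cells was added after the data were seen.

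On simulated data, counts were drawn from 1 mean profile pooled over all filtered cells of both libraries, with 200 genes made different. The depths were those of all filtered cells, 27357540 and 35852799 UMIs, larger than those of the endothelial-like class. Of the simulated genes, 3759 reached 20 CPM. All 67 genes simulated at 2.5-fold and all 66 at 4-fold passed a 2-fold minimum, as did 0 of the 67 genes simulated at 1.5-fold and 0 of the unaltered genes. The simulated fold lay inside its interval for 97.0%, 95.5% and 92.4% of the genes at 1.5, 2.5 and 4-fold, and for 95.2% of the unaltered ones. These simulations hold counting error alone.

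Alternatives chosen in advance were a stricter and no cell filter, doublets kept, other resolutions, 1000 variable genes with 15 components, each library clustered alone and classes from marker UMIs per cell. For folds they also included a TMM factor from edgeR 4.0.16 in R 4.3.3 (used for scaling only), totals without mitochondrial, ribosomal and haemoglobin genes, means of per-cell CPM, matched cluster shares and other CPM minimums. Removal of the 5% of cells with the highest Scrublet scores, inclusion of all clusters with endothelial markers and exclusion of the cluster led by G2/M genes were added after the data were seen. Other software was python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.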

Results

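The transcriptomes of fli1:EGFP-positive cells were measured in hearts of zebrafish in which cardiomyocytes with active β-catenin signalling carried a nitroreductase fused to mCherry. Nitroreductase converts MTZ into a toxic product, so MTZ ablates the cells that carry it. Fish entered treatment at 1 month of age and were exposed for 12 h every other day for 4 weeks, either to 5 mM MTZ or to DMSO. The comparison asked how endothelial cells of the heart differ when these cardiomyocytes are removed. Each group was 1 library, so no difference below has a replicate check, and the intervals in parentheses are 95% intervals that cover counting error only. The DMSO library held 27860164 UMIs over 6206 barcodes with a median of 4142 UMIs, and the MTZ library 36400801 UMIs over 6709 barcodes with a median of 4755. After filtering, 5862 DMSO and 6407 MTZ cells remained.

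Clusters with endothelial markers made up 93.4% of DMSO cells (92.7 to 94.0%) and 90.8% of MTZ cells (90.1 to 91.5%). Cardiomyocyte-like cells, defined by myl7, cmlc1 and actc1a, were 65 of the DMSO cells (1.11%, 0.857 to 1.41%) and 186 of the MTZ cells (2.90%, 2.51 to 3.34%). Fibroblast- or epicardial-like cells were 1.23% and 1.53%, macrophage-like cells 1.23% and 1.69%, thrombocyte-like cells 2.25% and 1.83%, and erythrocyte-like cells 0.546% and 0.780% of the DMSO and MTZ cells. The small shares depended on the settings. With the stricter cell filter, cardiomyocyte-like cells were 0.164% and 0.796%, thrombocyte-like cells 1.103% and 0.852%, and erythrocyte-like cells 0.211% and 0.315%. The macrophage-like class of 180 cells also held lymphoid cells: at double resolution 101 cells were lymphoid-like, and macrophage-like cells were 0.512% and 0.858%. Macrophage-like cells were 0.324% and 0.437% by marker UMIs per cell, and 0.233% and 0.329% without the highest Scrublet scores. These shares were set in part by the sort for live green cells, which removes most cells outside the fli1 lineage, and by the lower limit of about 500 UMIs per deposited barcode. Of the clusters with endothelial markers, 1 mixed with cardiomyocyte genes (170 and 234 cells, 2.90% and 3.65%) was kept out of the endothelial-like class. Cluster 2, led by edn1, ptgs2a and vcam1b, also stayed unnamed because nppb of the cardiomyocyte list stood among its leading genes, and it held 617 of the DMSO and 1021 of the MTZ cells. A further unnamed cluster led by angptl7 and mgp held 14 and 30 cells.

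**Figure D1:**
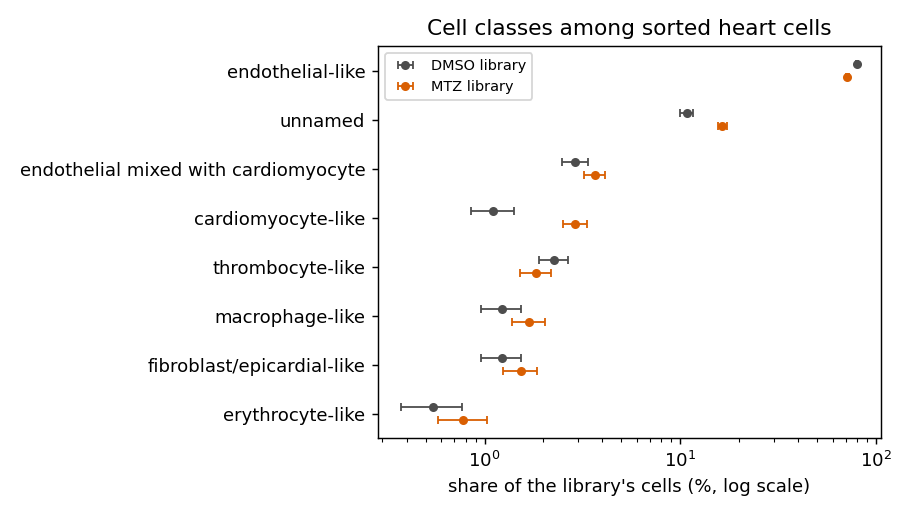
Share of filtered cells in each class (percent, log scale) in the DMSO and MTZ libraries, 1 library each; points are shares and bars are exact binomial 95% intervals for counting error only. Unnamed cells pool cluster 2 with a cluster of 14 and 30 cells. Cardiomyocyte-like cells stood at 1.11% and 2.90%, and endothelial-like cells at 80.0% and 71.2%. Cluster 2, which had endothelial markers, is not part of the endothelial-like class.

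The endothelial-like class, which left out cluster 2, held 4688 DMSO cells (80.0%) with 21095628 UMIs and 4563 MTZ cells (71.2%) with 23941363 UMIs. The proportions of its clusters differed between the 2 libraries. A cluster led by nppc, flt1 and kcne4 held 885 DMSO and 1327 MTZ cells, and a cluster led by ifitm1 and nppb held 93 and 328. Conversely, a cluster led by gbp and sesn1 held 641 and 328 cells, a cluster led by igfbp6b and heat shock genes held 609 and 192, and a cluster led by the interferon-induced genes rsad2 and isg15 held 361 and 125. A cluster led by egln3, ddit4 and hsp70.1 held 549 and 712 cells. Clusters led by S-phase and by G2/M genes were part of the class as well. The markers of the sort and of Wnt signalling were read first. Expression of fli1a was 257 CPM in the DMSO library and 259 CPM in the MTZ library (ratio 1.00, 0.969 to 1.04), and its paralog fli1b was at 59.7 and 46.9 CPM (ratio 0.785, 0.724 to 0.852). The Wnt target axin2 had 231 and 150 UMIs (ratio of CPM 0.572, 0.463 to 0.706), whereas lef1 was at 1.90 and 2.34 CPM, a ratio whose interval included 1 (0.808 to 1.90).

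Among endothelial-like cells, the MHC class I gene mhc1uba was 8.71-fold higher in the MTZ library (7.60 to 10.0), at 95.7 CPM, on 232 DMSO and 2292 MTZ UMIs. The interferon-inducible membrane protein gene ifitm1 was 3.52-fold higher (3.25 to 3.82), the lysyl oxidase gene loxl2a 3.49-fold (3.12 to 3.91), and the potassium channel subunit gene kcne4 3.23-fold (3.09 to 3.37). The activin subunit gene inhbaa was at 10.7 CPM in DMSO and 33.9 CPM in MTZ cells, and serpinf1, which encodes pigment epithelium-derived factor, at 25.3 and 73.2 CPM. The tight junction gene cldn5b was 2.70-fold higher (2.54 to 2.87), at 173 CPM in the MTZ library. It was higher too in cluster 2, at 394 and 689 CPM, and in erythrocyte-like cells, at 24.2 and 131 CPM. RNA carried over from other cells was not separated from its value. The natriuretic peptide gene nppc was the most abundant of the named higher genes, at 730 and 1812 CPM (2.48-fold), and with cluster shares matched its fold was 1.96. The TNF receptor family gene tnfrsf19 was 2.85-fold higher and egln3, a prolyl hydroxylase that acts on hypoxia-inducible factor, 2.62-fold higher (2.40 to 2.87). The mitotic genes aspm, at 6.16 and 20.1 CPM, and ube2c, at 7.73 and 22.9 CPM, reached 20 UMIs in a single endothelial cluster, the one led by G2/M genes. Matched cluster shares also lowered the folds of ifitm1 to 2.56, kcne4 to 2.55 and inhbaa to 2.64, outside their intervals. The same held for cldn5b at 2.08, aspm at 2.42 and ube2c at 2.22. Folds of mhc1uba, loxl2a, serpinf1, tnfrsf19 and egln3 stayed inside theirs. Clusters were made from both libraries together, and some were led by genes given here, such as ifitm1, kcne4, nppc, gbp and rsad2. Matching the shares of such clusters can by itself move the folds of these genes. Matched folds therefore do not separate cluster mixture from expression.

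The claudin gene cldn17 was 3.84-fold lower in the MTZ library, at 25.4 CPM against 97.6 CPM in the DMSO library (ratio 0.261, 0.238 to 0.286). The gene gbp was 2.44-fold lower, the keratin genes krt4 and krt91 were 2.34-fold and 1.96-fold lower, and the semaphorin gene sema7a was 2.25-fold lower. The heat shock gene hsp70l was at 2420 CPM in DMSO and 1447 CPM in MTZ cells (ratio 0.598, 0.590 to 0.606). The remaining named lower genes differed less than 2-fold. They were the transporter gene abcc2 (1.80-fold lower), the glutathione transferase gene gsta.1 (1.91-fold), bnip4 (1.81-fold), rnf44 (1.78-fold), the cyclin D1 gene ccnd1 (1.66-fold) and the growth factor binding protein gene igfbp6b (1.64-fold). The ratio for igfbp6b was 0.612, and it was 0.726 with cluster shares matched. Matching also moved gbp to 0.513, krt91 to 0.563 and hsp70l to 0.644, outside their intervals, and left the other named lower genes inside theirs. Of the 24 named genes, 23 differed at least 1.5-fold in the same direction in 0.5 or more of the endothelial clusters with 20 UMIs of the gene. The exception was igfbp6b, in 4 of 11. These genes had been chosen from the sum over the same clusters, so this count is no separate check. Of 3896 genes at 20 CPM or more, 30 were at least 2-fold higher and 6 at least 2-fold lower in the MTZ library, and the median log2 fold over these genes was 0.05. Reads of mhc1uba, the hsp70 genes and the keratin genes can be shared with near-identical copies, so their values are uncertain.

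**Figure D2:**
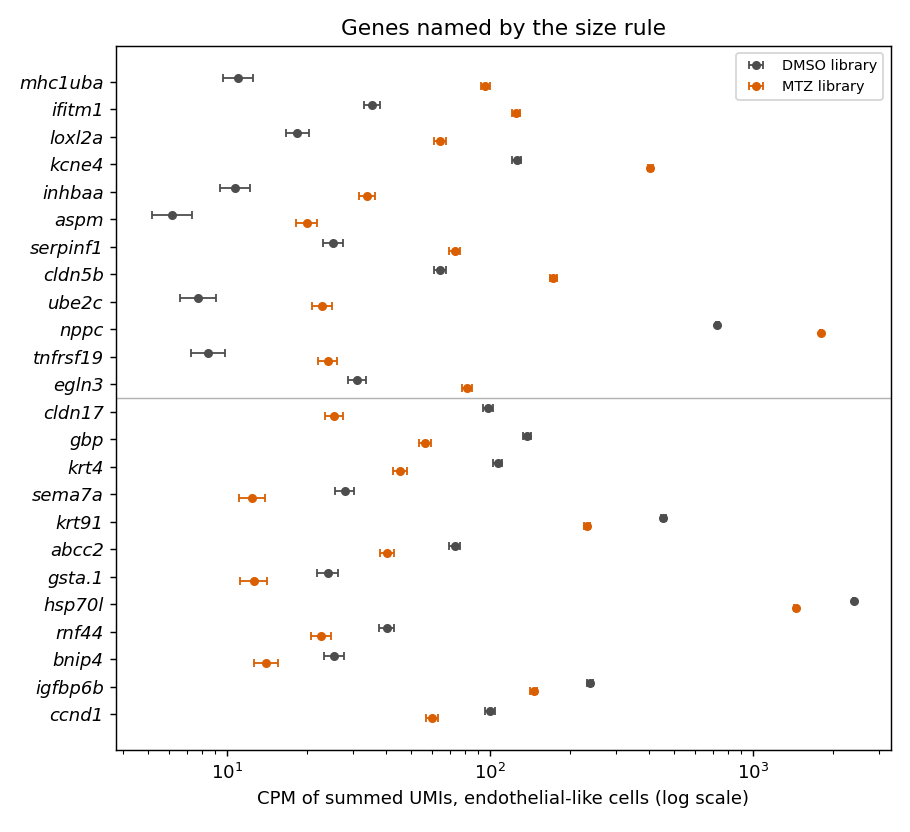
CPM of summed UMIs (log scale) of the 24 genes named by the size rule in endothelial-like cells, with 12 higher in the MTZ library above the line and 12 lower below it; points are the 2 libraries and bars are exact Poisson 95% intervals for counting error only. The widest gap was that of mhc1uba, 8.71-fold.

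Genes of G2 and M phase were higher together in MTZ endothelial-like cells. Of 18 measured members of this list, 15 were at least 1.5-fold higher and 0 lower, with a median log2 fold of 1.52 (1.34 to 1.63) that lay at the percentile 100 of random lists. The topoisomerase gene top2a was at 4.69 CPM in DMSO and 19.2 CPM in MTZ cells, cdk1 at 1.80 and 8.27 CPM, and nusap1 at 4.27 and 14.9 CPM. Without the cluster led by G2/M genes, which held 192 DMSO and 224 MTZ cells, the median was 0.16. Of 15 measured S-phase genes, 0 differed 1.5-fold; their median was 0.16 (percentile 95.7), and rpa2 stood at 18.7 and 23.9 CPM. Thinned to 2000 UMIs, 2250 of 4387 DMSO cells (51.3%) and 2514 of 4432 MTZ cells (56.7%) had UMIs of at least 2 G2/M genes, with 301 and 131 shallower cells left out; unthinned, the shares were 78.1% and 85.9%. Those shares rested on tuba8l4, hmgb2a and hmgb2b, which were detected in 71.6%, 51.7% and 26.8% of thinned DMSO cells. With these 3 left out, 36 DMSO cells (0.821%, 0.575 to 1.13%) and 75 MTZ cells (1.69%, 1.33 to 2.12%) had UMIs of at least 2 of the other 22 genes, and unthinned 1.26% and 2.48% did. In cluster 2, 0 of 594 DMSO and 0 of 1011 MTZ cells did, with intervals up to 0.619% and 0.364%. Its median depths were 4401 and 5104 UMIs, beside 4194 and 4723 UMIs in the endothelial-like class. In the cluster led by G2/M genes, 30 of 185 DMSO (16.2%) and 68 of 219 MTZ cells (31.1%) did. In small classes, 5 of 64 DMSO and 4 of 103 MTZ macrophage-like cells and 2 of 32 and 4 of 50 erythrocyte-like cells did. The summed CPM of the 22 genes was 81.9 and 225 (2.75-fold, 2.60 to 2.90), and that of the S-phase genes 311 and 345 (1.11-fold, 1.07 to 1.15).

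The 4 measured Wnt/β-catenin targets were lower in the MTZ library, with a median log2 fold of -0.67 (-0.82 to -0.51, percentile 0.01). At least 1.5-fold lower were 3 of them, axin2, nkd1 and ccnd1, and myca was at 13.3 and 9.61 CPM. Most listed targets lay below 5 CPM and were left out, among them lef1, which was not lower. Over all lists 55 genes differed 1.5-fold, and 38 of them still did with cluster shares matched; of the Wnt targets nkd1 did not (ratio 0.678). Inflammatory and NF-κB genes had 6 of 19 members at least 1.5-fold higher and 0 lower (median 0.36, percentile 100). Among them the prostaglandin synthase genes ptgs2a and ptgs2b were at 49.8 and 84.3 CPM in DMSO and at 89.2 and 148 CPM in MTZ cells (1.43-fold and 1.29-fold with cluster shares matched), and il11a at 2.18 and 6.27 CPM. The tumour necrosis factor gene tnfb was at 1.61 and 12.7 CPM and the chemokine gene cxcl11.1 at 1.94 and 11.6 CPM, but 1 MTZ cell held 245 of the 305 tnfb UMIs and 1 held 157 of the 278 cxcl11.1 UMIs. Without the highest cell of each library tnfb was 2.203-fold and cxcl11.1 3.95-fold higher, with the stricter cell filter 1.42-fold and 2.44-fold, and with cluster shares matched 14.1-fold and 9.57-fold. Hypoxia targets had 2 of 11 members higher, egln3 and igfbp1a (119 and 359 UMIs; 2.66-fold, and 4.23-fold with the stricter cell filter), and 1 lower, bnip4, with a median of 0.38 (percentile 99.97) that was 0.20 with cluster shares matched. Glycolytic genes had 1 of 20 members higher, hk1 (1.42-fold with cluster shares matched), and a median of 0.20 (percentile 99.3). VEGF receptors and sprouting genes had 3 of 16 higher, among them the VEGF receptor gene flt1 at 256 and 422 CPM, and 1 lower, the apelin receptor gene aplnrb at 15.4 and 8.44 CPM (median 0.21, percentile 99.1); with cluster shares matched the median was 0.13, and of the higher genes only flt1 stayed past 1.5-fold. In the CXCR4 and CXCL12 list 2 members were measured and neither differed 1.5-fold (median 0.50, percentile 97.1), with ackr3b at 70.9 and 98.6 CPM. The 4 measured TGF-β targets had a median of 0.31 (percentile 95.8), and the 10 coagulation genes, with serpine2 at 4.69 and 11.4 CPM, a median of 0.15 (percentile 90.5).

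Secreted growth factor genes included 5 of 23 members that were higher, among them igfbp7 2.06-fold higher, the neuregulin gene nrg1 at 2.09 and 6.98 CPM (in 21 DMSO and 25 MTZ cells) and inhbaa, and 1 lower, bmp2a at 9.24 and 5.97 CPM (ratio 0.703 with cluster shares matched; median 0.04, percentile 57.1). Genes of the p53 and apoptosis list had 3 of 16 higher, cdkn1a at 57.6 and 87.6 CPM, gadd45bb and phlda3, and 1 lower, sesn1 at 358 and 224 CPM (median 0.16, percentile 94.8). With cluster shares matched only phlda3 of these stayed past 1.5-fold, with cdkn1a at 1.40, gadd45bb at 1.41 and sesn1 at 0.746. Of 18 interferon response genes, mhc1uba was higher, rsad2 and stat1b were lower, and 15 lay within 1.5-fold (median 0.03, percentile 42.8); rsad2 was at 27.0 and 16.1 CPM, and its ratio of 0.598 turned to 1.29 with cluster shares matched, where that of stat1b was 0.796. Flow-responsive genes had 2 of 13 higher, nppc and klf4 (22.4 and 38.2 CPM), with a median of 0.04 (percentile 61.6). Matrix genes had 2 of 23 higher, loxl2a and timp2b (37.2 and 58.8 CPM, 1.498-fold with cluster shares matched; median 0.02, percentile 29.4), and junction genes 1 of 14, cldn5b (median -0.04, percentile 11.3). Lipid-handling genes had 1 of 7 higher, fabp3 at 6.30 and 10.2 CPM, with the lipase gene lpl at 541 and 373 CPM (median -0.02, percentile 31.4). Retinoic acid and epicardial genes had 1 of 7 lower, nr2f2 at 108 and 69.6 CPM (ratio 0.706 with cluster shares matched); the median of -0.16 (percentile 4.92) turned to 0.08 over all clusters with endothelial markers and to 0.14 at a minimum of 50 CPM.

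The immediate early and dissociation stress list had a median of -0.11 (-0.13 to -0.03; percentile 0.145), with 1 of 25 members at least 1.5-fold lower and 0 higher. That member was hspb1, at 1142 and 761 CPM (ratio 0.666, and 0.765 with cluster shares matched); the chaperone gene hsp90aa1.2 was at 1662 and 1133 CPM, and junbb at 1878 and 2783 CPM. As the mean of per-cell CPM the list's median was -0.0013. None of 13 mitochondrially encoded genes differed 1.5-fold, with a median of -0.17 (percentile 0.12) and mt-co2 at 3379 and 2913 CPM. Genes of nuclear encoded oxidative phosphorylation had 1 of 32 higher, cycsb at 99.2 and 165 CPM (1.46-fold with cluster shares matched; median 0.13, percentile 94.7). In 5 further lists, 0 members differed 1.5-fold. These were 9 BMP/SMAD targets (median -0.08, percentile 6.28), 14 Notch pathway genes (0.11, percentile 84.8), 12 FGF/ERK targets (-0.11, percentile 2.49), 11 genes of endothelial to mesenchymal transition (-0.03, percentile 19.3) and 2 class II antigen presentation genes (-0.01, percentile 51.1). Within these, id1 was at 247 and 223 CPM, dlc at 10.0 and 13.4 CPM, the ERK phosphatase gene dusp5 at 430 and 632 CPM, snai1a at 13.5 and 10.1 CPM and cd40 at 10.4 and 11.6 CPM. Markers of other cells and of endothelial subtypes were summed within the endothelial-like class. Of other cells, cardiomyocyte markers summed to 1644 CPM in DMSO and 2381 CPM in MTZ cells (1.45-fold), erythrocyte markers to 259 and 144 CPM, and mural markers to 185 and 484 CPM. Of the endothelial subtypes, endocardial markers had the largest sums, at 17271 and 16947 CPM, followed by coronary vascular markers at 10738 and 11658 CPM. Venous markers were at 444 and 341 CPM, and arterial markers at 383 and 521 CPM. Without cldn5b the arterial sum was 319 and 348 CPM, and without kcne4 the mural sum was 59.2 and 77.9 CPM.

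**Figure D3:**
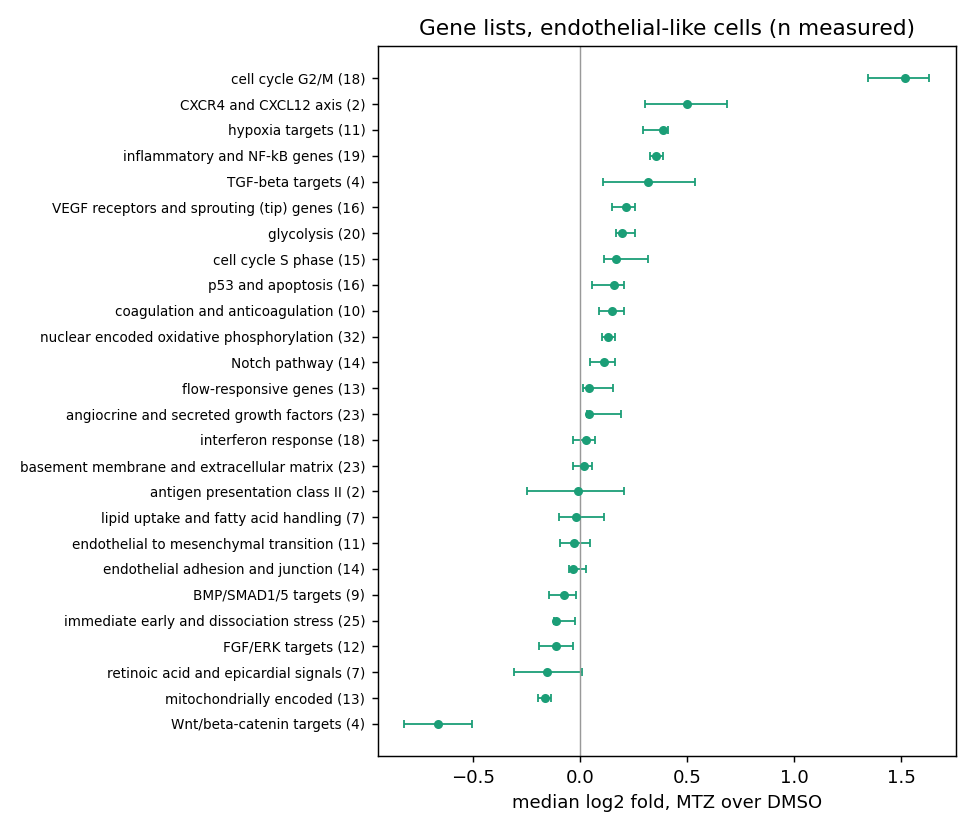
Median log2 fold (MTZ over DMSO) of 26 gene lists in endothelial-like cells, with the number of measured members beside each name; bars are 95% intervals from Poisson draws for counting error only. The G2/M list stood at 1.52 and the Wnt/β-catenin list at -0.67.

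Cluster 2 was compared on its own, with 2877003 UMIs in DMSO and 5637969 UMIs in MTZ cells. Its cardiomyocyte markers differed too, at 1709 and 2678 CPM (1.57-fold). Its mural markers were at 90.4 and 177 CPM and its arterial markers at 553 and 835 CPM, but at 37.2 and 29.6 CPM without kcne4 and at 159 and 146 CPM without cldn5b. The gene mhc1uba was 19.6-fold higher in the MTZ library (interval up to 38.3), on 12 DMSO and 462 MTZ UMIs. The gene crhbp, for a corticotropin-releasing hormone binding protein, was 4.07-fold higher (2.91 to 5.83), serpinf1 4.18-fold, ifitm1 2.79-fold and kcne4 2.76-fold. In the other direction, cldn17 was 3.55-fold, abcc2 3.30-fold, krt91 2.70-fold, gbp 2.86-fold and the aquaporin gene aqp1a.1 3.00-fold lower. Of 3839 genes at 20 CPM or more, 31 were at least 2-fold higher and 13 at least 2-fold lower, and with totals without mitochondrial, ribosomal and haemoglobin genes, where more genes reach 20 CPM, 47 and 25. Of the 31 higher genes, 8 (chst1, hif1al, ifitm1, kcne4, loxl2a, mhc1uba, serpinf1 and tnfrsf19) also passed 2-fold in the endothelial-like class. Of the 13 lower genes, 4 did, cldn17 and gbp among them.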

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

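Removal of the highest Scrublet scores, all clusters with endothelial markers, the class without its G2/M cluster, sums without the highest cell of each gene and the narrow G2/M count were chosen only after results were seen. No paired analysis was possible because each group had 1 library, and doublets kept equals the reported setting, since Scrublet called none. For 93 named genes over 8 settings, 668 endothelial folds stayed inside their counting interval, 75 moved out of it, and 1 of the genes at least 1.5-fold different turned: rsad2, 0.598 in the reported sum, was 1.29 with cluster shares matched. Of the 75, 38 came from matched cluster shares, 10 from the stricter cell filter and 3 from leaving out the highest cells; 1, the less than 1.5-fold different cxcl12a, passed to the other side of 1 as the mean of per-cell CPM. Settings that recluster the cells were not run for cluster 2, whose number does not carry over. Depth limits genes under 20 CPM most, and small classes hold too few UMIs for most lists. The causes of the shifts below were not tested.

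Clusters with endothelial markers held 95.5% of DMSO and 94.2% of MTZ cells under the stricter filter, 92.1% and 89.8% without a filter, 94.6% and 92.1% at double resolution, 95.2% and 92.7% by marker UMIs per cell, and 94.2% and 91.5% without the highest Scrublet scores. The endothelial-like class held 78.7% and 69.1% at 0.5 times the resolution, 84.2% and 74.3% at double resolution, 83.8% and 74.7% with 1000 variable genes, 81.1% and 75.9% with each library clustered alone, 95.2% and 92.7% by marker UMIs, and 81.8% and 73.3% without the highest Scrublet scores. Cardiomyocyte-like cells were 0.164% and 0.796% under the stricter filter, 0.631% and 2.26% at either other resolution, 0.768% and 2.42% with 1000 variable genes, 0.785% and 2.28% clustered alone, and 0.664% and 2.33% without the highest Scrublet scores, and 3.42% of MTZ cells by marker UMIs. The share with 2 G2/M genes was 78.1% and 85.9% unthinned, 22.9% and 27.4% at 1000 UMIs, 89.7% and 91.9% with 1 gene needed, and 12.4% and 16.0% with 3. The narrow share was 1.26% and 2.48% unthinned, 4.31% and 6.59% with 1 gene, 0.524% and 1.26% with 3, and 1.14% of MTZ cells at 1000 UMIs. In each of these pairs the order of the 2 libraries was as reported.

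Of endothelial genes, 882 were 2-fold higher and 623 lower with no CPM minimum, where most rest on few UMIs, and 13 were higher at 50 CPM. In cluster 2 these counts were 943 and 584 with no minimum, 8 and 7 at 50 CPM, and 47 and 25 with totals without mitochondrial, ribosomal and haemoglobin genes. With cluster shares matched, list medians were 0.13 for VEGF and sprouting genes, 0.20 for hypoxia, 1.16 for G2/M, 0.24 for NF-κB, -0.13 for stress and 0.14 for glycolysis. As means of per-cell CPM they were 0.43 for hypoxia, 1.1999 for G2/M, 0.39 for NF-κB and -0.0013 for stress. Over all clusters with endothelial markers they were 0.14 for VEGF, 0.40 for NF-κB and 0.15 for glycolysis. The G2/M median was 0.16 without the G2/M cluster, 0.37 at 50 CPM and 1.64 without the highest cell of each gene. The stress median was -0.14 under TMM scaling, with totals without abundant genes and under the stricter filter, and -0.015 with no CPM minimum. Wnt targets were at -0.49 with no CPM minimum, hypoxia at 0.43 at 50 CPM, glycolysis at 0.16 with totals without abundant genes, and mitochondrial genes at -0.10 without a cell filter. These medians kept their sign in each setting, whereas 9 lists with medians nearer 0, among them the interferon, class II, lipid and retinoic lists, turned sign in at least 1 setting.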

Other observations

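The tests of depth, of free RNA, of a strain variant and of interferon induction below, and the sub-clusters, were chosen only after results were seen. Several of the named endothelial genes also differed in cells of other classes, with few cells behind each value. Fibroblast- or epicardial-like cells (72 and 98 cells) had ifitm1 at 296 CPM in DMSO and 1119 CPM in MTZ cells (3.78-fold, 3.24 to 4.43; 5.36-fold without the highest cell of each library), and loxl2a at 123 and 310 CPM. Their cldn5b was at 19.2 and 248 CPM, in 5 and 27 cells, but erythrocyte-like cells, read as a background with most UMIs from haemoglobin genes, went the same way, with cldn5b at 24.2 and 131 CPM, ptgs2a at 15.5 and 109 CPM and ifitm1 at 6.91 and 30.8 CPM. RNA carried over from other cells was not separated from these differences. Macrophage-like cells (72 and 108 cells) held 0 ifitm1 UMIs in DMSO and 160 in MTZ cells. With the DMSO count set to a floor of 3 UMIs this was 22.5-fold, which is not the lower end of an interval. The 160 UMIs came from 18 cells, and 47 of them from 1 cell. The macrophage-like class held another mixture in each library, with erythrocyte markers at 252 and 15680 CPM, neutrophil markers 3.84-fold higher and its own markers at 0.671 times the DMSO level in the MTZ library. In cardiomyocyte-like cells cldn17 was at 73.8 and 38.1 CPM, but endocardial markers went with it, at 6770 and 3662 CPM. Sub-clusters of a small endothelial cluster led by frzb held rare cell types. A lymphatic-like one with lyve1a, lyve1b, stab2, mrc1a and prox1a had 8 DMSO and 15 MTZ cells. A valve endocardial-like one with has2, vcana, klf2a and klf2b had 7 and 14. It also held the endocardial markers hand2, nfatc1 and nrg1 and the cardiomyocyte marker tnnt2a, and the valve marker wnt9a led another sub-cluster. A coronary vascular-like one with apln, aplnra, esm1 and plvapb had 7 and 8, and it also held the arterial markers cxcr4a, efnb2a, dll4, dlc and cldn5b.

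In cluster 2, the median log2 fold of 4 measured Wnt targets was again below 0, at -0.76 (percentile 0.08), with nkd1 1.91-fold and ccnd1 1.65-fold lower. The intervals of axin2 (ratio 0.572, 0.321 to 1.02) and myca (0.883, 0.533 to 1.49) included 1, and lef1 had 4 and 8 UMIs (ratio 1.02). Retinoic acid and epicardial genes had 3 of 8 members at least 1.5-fold lower (median -0.38, percentile 0.04), among them cyp26b1, which degrades retinoic acid, at 21.6 and 9.05 CPM. In the other direction, aldh1a2 of this list was 1.38-fold higher (1.29 to 1.49). FGF/ERK targets had 4 of 12 lower (median -0.23, percentile 0.69), with etv5b at 21.9 and 13.8 CPM, whereas dusp5 was 1.42-fold higher, at 1042 and 1478 CPM. BMP targets had 3 of 9 lower, with id3 at 187 and 122 CPM. Of 25 stress genes, 4 were lower and 1 higher (median -0.24, percentile 0), with hsp90aa1.2 at 1054 and 496 CPM. S-phase genes had 5 of 9 higher (median 0.72), on few UMIs such as 7 and 32 of mcm4. Matrix genes had 5 of 24 higher, with loxl2a at 34.4 and 95.4 CPM.

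The gene mhc1uba was higher and cldn17 lower in the MTZ library in several cell classes, in 8 of 8 pairs of gene and other class with 20 UMIs, of which cldn17 in cardiomyocyte-like cells followed the lower endocardial markers there. Interferon or class I induction as a group is argued against by the interferon list, whose median log2 fold was 0.028 (-0.03 to 0.07) and 0.13 with cluster shares matched, where rsad2 turned to 1.29-fold higher, and by b2m at 1001 and 1051 CPM; induction of single genes is not excluded, since ifitm1 was higher in 5 of 5 other classes with 20 UMIs. Free RNA of endothelial cells stays open: the MTZ ratio of mhc1uba to cldn17 in macrophage-like cells was 5.10 times that in thrombocyte-like cells (2.23 to 11.7), but these were the extremes of 4 classes. The ratio in macrophage-like cells (8.93, 5.13 to 16.8) lay above that in endothelial-like cells (3.76, 3.44 to 4.12), whereas those in thrombocyte-like cells (1.75, 0.915 to 3.46) and fibroblast- or epicardial-like cells (4.92, 2.68 to 9.74) overlapped it. A strain or donor variant could also give such a shift in all classes, since pools of fish can carry different alleles of MHC genes, and cannot be told apart from an effect of MTZ or of ablation, itself untested, without genotypes or replicate pools.

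The higher G2/M genes in MTZ endothelial-like cells may reflect more dividing cells, a hypothesis that 1 library per group leaves untested. The cluster led by G2/M genes held similar shares of all cells of each library, 3.28% in DMSO (2.83 to 3.76%) and 3.50% in MTZ (3.06 to 3.98%). Inside it the thinned narrow share was 16.2% in DMSO and 31.1% in MTZ cells. The difference thus lay mainly within this cluster, but its weight in the class differed too. It held 998671 of 21095628 DMSO and 1527012 of 23941363 MTZ UMIs of the class. With cluster shares matched, top2a was 3.07-fold, cdk1 3.57-fold and nusap1 2.64-fold higher, instead of 4.09-fold, 4.59-fold and 3.50-fold. All 15 genes of the list past 1.5-fold stayed past it. A difference in depth is argued against by the thinned narrow share, which was 2.06 times as high in the MTZ library (1.37 to 3.16). Free RNA from cycling cells stays open. In cluster 2, 0 of 1011 thinned MTZ cells (at most 0.364%) had 2 narrow G2/M genes, below the 1.69% of endothelial-like cells (1.33 to 2.12%). This met the outcome set against free RNA, but it cannot decide, because the clustering had itself gathered such cells. In the cluster led by G2/M genes, 68 of 219 thinned MTZ cells had them. Of macrophage-like and erythrocyte-like MTZ cells, whose own division was not tested, 4 of 103 and 4 of 50 had them. Doublets stay open: the ratio was 2.05 (1.35 to 3.16) without the highest Scrublet scores, which met the outcome set beforehand for excluding them, but a score that called 0 doublets may separate nothing. The S-phase sum differed 1.11-fold, so the difference lay mainly in the G2/M genes.

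Heat shock genes of the stress list were lower in MTZ endothelial-like cells, with 6 of 7 measured members at a ratio below 1. Their median log2 fold was -0.44 (-0.46 to -0.43). Of these members only hspb1 was at least 1.5-fold lower, and it was not with cluster shares matched (ratio 0.765). A handling stress that moves heat shock and immediate early genes alike is argued against by the 18 immediate early members, whose median was 0.018 (0.0022 to 0.04) and whose lowest was -0.27. Another mixture of endothelial clusters could account for part of it, since the heat shock median was -0.29 with cluster shares matched. How large that part is cannot be told apart from lower expression, because heat shock genes themselves lead some of these clusters. An effect of MTZ or of ablation stays untested.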
